A study of Mus musculus with 2 samples.

How the data were processed

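RNA of cultures labelled TH9, of 2 genotypes, was hybridised to 1-colour (Cy3) mouse gene expression arrays, 1 array per genotype. Per the labels, sorted naive CD4 T cells were activated with 2 µg/ml anti-CD3, 2 µg/ml anti-CD28 and 100 U/ml human IL-2 and cultured with 10 ng/ml IL-4 and 2 ng/ml TGFβ1. The sample descriptions give 5 days of culture and the treatment protocol 5 to 6. Groups were taken from the genotype label. The arrays were scanned and extracted with Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes, and per the headers both arrays came from the same slide and the same scan, so slide and scan do not differ between the genotypes.

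The deposited scanner files give each spot's processed signal, an intensity that the scanner software subtracted background from within the array, per the file headers, with an error of the same unit, the median pixel intensity of the spot and of its local background, and flags for spots above background, saturated or irregular. The deposited value table holds log2 values of the same arrays. Set against the scanner signal they rise with it on a log2 scale with equal medians of 5.36 in both columns, and the normalization behind them is not given in the sources used here, nor is any centring. Its highest value was 17.7 in the wild-type column and 46.7 in the knockout column, while the highest log2 scanner signal of a single-spot probe was 17.7 and 17.6.

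The main value was the log2 processed signal minus the 75th percentile of each array over its gene probes. Control spots and spots with an outlier flag (228 and 138 of 43020 gene spots) were left out, which removed 18 probes altogether. No gene spot was saturated. Spots of the same probe were averaged, and the difference is knockout minus wild-type. Probes carry accessions and no gene names in the files, and 27220 of 39411 probes matched a gene through an unversioned RefSeq accession in a table of the GRCm38.p6 assembly, giving 20651 genes. The headers name another build, so no coordinates are printed. The 12191 unmatched probes were not analysed here. A gene was represented by its probe with the highest mean signal among those well above background on at least 1 array, and 5472 genes had several probes. A gene counted as higher or lower if that probe was well above background on both arrays and differed by at least 1 on the log2 scale. Genes above background on 1 array only were counted apart, with a bound from the bright signal against the higher of the dim array's lowest signal well above background and the dim probe's own.

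No test between the genotypes was possible with 1 array each, and no p-value was computed. Gene lists fixed before the data were examined (32 lists, of which 31 had at least 3 measured members, 485 of 493 genes matched to a probe) were described by the median difference of their members and its percentile among 10000 random lists of the same size, matched on mean signal in 20 bins over genes well above background on at least 1 array. A list outside the central 95% of these was called as standing apart. That held for 10 lists, 8 higher and 2 lower, where 1.55 of 31 would be expected for independent genes, and genes of a list are not independent. Further lists were written after a first look at the data but before their own values were seen, for organ-restricted genes, macrophages of red pulp and lymph node, plasma cells, lymphoid stroma and endothelium, and genes of T and B cell zones.

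The genes named were chosen by a rule written before the data were examined. It takes Sirt1, Il9, Irf4, Spi1, Batf, Gata3, Foxp3, Tbx21, Hif1a and Myc, then the 12 highest and 12 lowest differences among genes with an established symbol, well above background on both arrays, whose measured probes share a sign and whose signal is at or above the median gene. It adds the 5 highest bounds in each direction, and from each list up to 4 members with the largest difference of at least 1, or the 2 largest where none reaches it, and up to 2 for cell type, quality and sample check lists. A few genes that the rule takes are not reported here. Other genes named were chosen after their values were seen, among them Ldha, Eno1, Gapdh, Pdk1, Gpi1, Alas2, Ms4a1 and Siglech.

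The value table was compared with the scanner signal over single-spot probes through a running median of 101 probes ordered by signal. The median intensity, background-subtracted signal, signal error and spot extent in the scanner files were compared with the processed signal after the data were seen, and spot extents below 30 or above 70 were counted. The alternatives were centring on the median, quantile normalization, loess between the arrays, normexp background correction with an offset of 50, the mean over probes, the authors' deposited log2 values, other filters and thresholds of 1.5-fold and 3-fold. The files used here hold no mean pixel intensity, so normexp ran on the median intensity. The functions were tested on simulated data. Among 12956 genes, 100.0% of 100 changed by 1.5 and 100.0% of 100 changed by 2.5 on the log2 scale were recovered past 2-fold. Among 14871 genes, 6.25% of 2000 lists of 15 unchanged genes fell outside the central 95%. The simulation held only scanner error. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. The number of arrays limits the precision.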

Results

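Gene expression was measured in mouse cultures of 2 genotypes labelled as T helper 9 (TH9) cells, the IL-9-producing type of CD4 T cell. Per the labels, naive CD4 T cells (CD4+TCR+CD62Lhi CD44lo) sorted from spleen and lymph nodes were activated through CD3 and CD28 with IL-2 and grown for 5 days with IL-4 and TGFβ1. The wild-type sample had 1 array, and so had the sample from mice carrying floxed Sirt1 alleles and a Cre recombinase driven by Cd4, called knockout here. The comparison asks which transcripts differ between the samples with these 2 genotype labels, and the series title concerns the bearing of SIRT1, an NAD-dependent deacetylase, on IL-9-producing cells. Each array carried 39429 gene probes, of which 399 were spotted 10 times, and 57.1% of the gene spots on the wild-type array and 65.3% on the knockout array were well above background. With 1 array per genotype no difference below has a replicate check, and no test between genotypes was possible.

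The targeted gene came first. The Sirt1 probe gave almost the same signal on both arrays, 3240 on the wild-type array and 2920 on the array labelled knockout, a difference of -0.08 on the log2 scale with a scanner error of 0.20. The labels do not say which exons the loxP sites flank and the position of the probe in the transcript is not given in the sources used here, so this probe cannot serve as a check of the label. Markers of cells other than T cells also gave signal on both arrays, as given below, so the Sirt1 signal need not be that of T cells alone. The array is called the array labelled knockout below, and every direction rests on that label. Il9, the cytokine that defines TH9 cells, was not well above background on either array, with a signal of 5.48 on the wild-type array and 7.36 on the array labelled knockout. The lowest signals well above background were 24.6 and 9.76, and no fold is given for Il9.

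Most regulators of the TH9 programme lay within 2-fold between the arrays. Irf4, a transcription factor that TH9 cells need, had a difference of -0.33 ± 0.21 (knockout minus wild-type, log2, scanner error), and Batf, its partner factor, one of 0.02 ± 0.20. Spi1, which encodes PU.1, was well above background on the array labelled knockout only, at least 1.17-fold higher there. Pparg, a nuclear receptor, was 2.81-fold higher on the array labelled knockout and Il17rb, the IL-25 receptor chain, 2.35-fold. With another background correction (normexp) these differences were 0.37 and -0.063 on the log2 scale, both within 2-fold. Of the 19 list members well above background on both arrays, 15 were higher and 4 lower, 2 were at least 2-fold higher, 0 were at least 2-fold lower and 17 lay within 2-fold. The list's median difference was 0.21, at percentile 97.0 of random lists matched on signal, just inside the central 95% taken as unremarkable. It stood apart by its mean (0.39, percentile 99.8), with all members whatever their background flag (percentile 97.9) and with members at their bound (97.6). The list stayed inside the central 95% with the mean over probes (median 0.080, percentile 75.65) and with normexp (0.26, percentile 88.12). The same held with only members well above background on both arrays and against random lists not matched on signal. Macrophage markers were mostly higher on the array labelled knockout too, as given below, so the values of this list need not be those of TH9 cells alone.

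Factors of other helper lineages were higher on the array labelled knockout in several cases. Tbx21, the TH1 master factor, was 2.32-fold higher (1.21 ± 0.20 on the log2 scale) and Ccl5, a chemokine of TH1 and cytotoxic cells, was 2.30-fold higher. Gata3, the TH2 master factor, had a difference of 0.54 ± 0.20, Maf was 2.14-fold higher and Il1rl1, the IL-33 receptor, was 2.5-fold higher, while Areg, encoding amphiregulin, was 2.45-fold lower. Areg was dim, with signals of 39.5 on the wild-type array and 15.4 on the other. The lowest signals well above background on these arrays were 24.6 and 9.76. Foxp3, the regulatory T cell factor, had a difference of 0.42 ± 0.21, which turned to -0.09 with normexp. The TH2 list had 2 members at least 2-fold higher, 1 at least 2-fold lower and 9 within 2-fold, with a median of 0.46 at percentile 99.2. That median turned to -0.27 with normexp, at percentile 84.0. The TH1 list had 2 of 13 members at least 2-fold higher and a median of 0.20 (percentile 92.7). The TH17 list had a median of 0.09 (percentile 65.8). No member of the regulatory T cell list passed 2-fold, Nrp1 with 0.80 (0.050 with normexp) and Capg with 0.57 differed most, and the median was 0.13 (percentile 76.4). Signal of CD8 and NK cell, macrophage and mast cell markers was higher on the same array, as given below.

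Genes of follicular helper cells were slightly lower on the array labelled knockout. Of 12 members, 10 were lower and 2 higher, all within 2-fold, and the median of -0.28 lay at percentile 0.440. The list no longer stood apart with normexp (median -0.021, percentile 3.34), with the mean (percentile 3.21) or against random lists not matched on signal (percentile 2.98). Pou2af1, a coactivator also abundant in B cells, had a difference of -0.54 and Tox2 one of -0.41. The naive and memory list had a median of 0.00 (percentile 35.5), with Igfbp4 2.32-fold higher and S1pr1, the receptor that lets T cells leave lymphoid organs, 2.04-fold lower. In the cytotoxic list 11 of 12 members were higher, 1 by at least 2-fold: Klrg1, an inhibitory receptor of effector cells, was 2.08-fold higher. The list's median was 0.37 (percentile 99.0). B cell markers were also mostly lower on this array, and NK cell markers higher.

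Secreted factors lay close to the edge of the matched range. Lif, a cytokine of the IL-6 family, was 3.39-fold higher on the array labelled knockout, a difference of 0.80 on the log2 scale with normexp. The median of the cytokine and chemokine list was 0.30 (percentile 97.8). With normexp it was -0.35, inside its matched range of -0.68 to -0.14 (percentile 69.3). The list lay inside the central 95% with quantile normalization (percentile 96.0), loess (95.4) and the authors' deposited table (94.4) too. Macrophage and mast cell markers were higher on the same array. Of the 15 members well above background on both arrays, 1 was at least 2-fold higher and 0 were lower by as much. The inhibitory and costimulatory receptors had a median of 0.05 (percentile 54.3), Havcr2 (TIM-3) with 0.85 and Cd28 with -0.81 differing most. The homing receptors and integrins had a median of 0.15 (percentile 84.9), and S1pr4 was 2.11-fold lower.

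**Figure D1:**
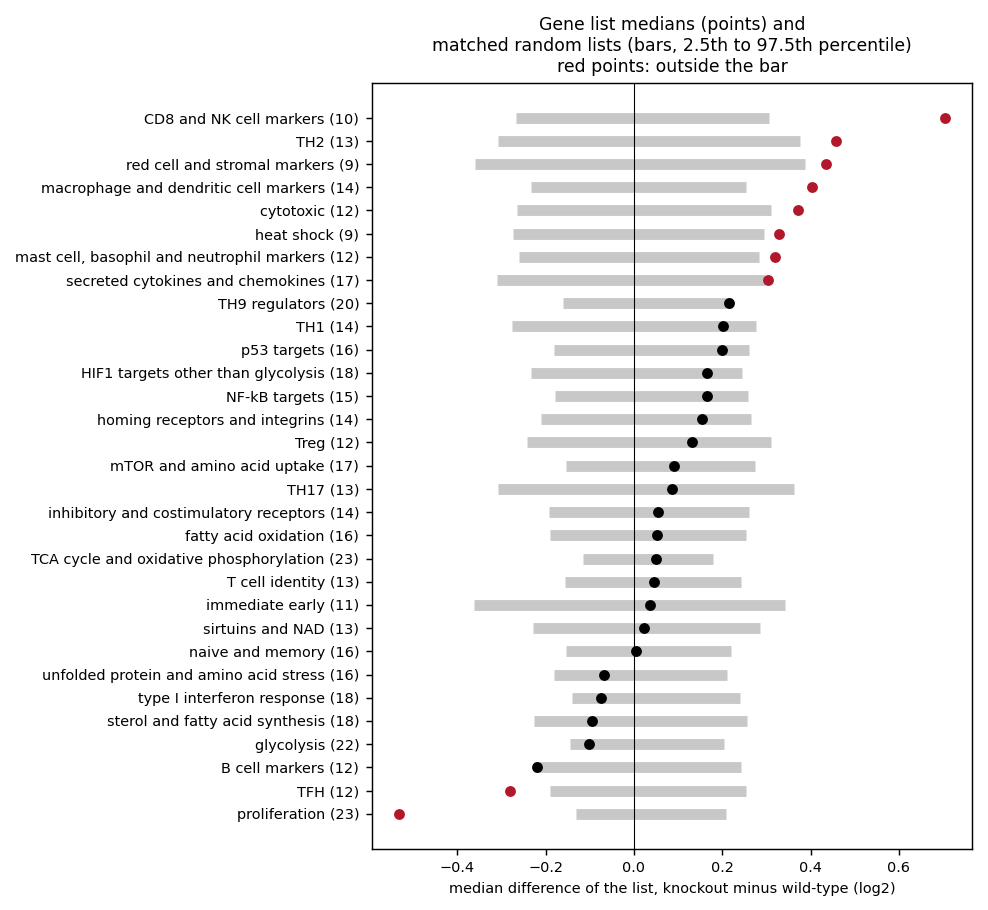
Median difference (knockout minus wild-type, log2, horizontal axis) of the 31 gene lists fixed before the data were examined that had at least 3 measured members. Each row is 1 list, with the number of members in parentheses. Grey bars span the central 95% of 10000 random lists matched on signal and red points lie outside the bar, with proliferation lowest at -0.53 and the CD8 and NK cell markers highest at 0.70.

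Glycolysis genes were all measured, and none differed by 2-fold in the processed signal scaled to the 75th percentile. Of 22 members, 9 were higher and 13 lower on the array labelled knockout, and 8 differed by less than their scanner error. Markers of cells other than T cells gave signal on both arrays, as given below, so these values need not be those of TH9 cells alone. Hif1a, which drives glycolysis genes in activated T cells, had a difference of -0.44 ± 0.20, and Myc, which drives them too, one of -0.26 ± 0.20. Slc16a1, a lactate transporter, had the lowest value at -0.90 and Pfkfb3, which makes the activator of phosphofructokinase, the highest at 0.82, although the second probe of Pfkfb3 gave -0.60. Pfkfb3 passed 2-fold after centring on the median (1.004) and with normexp (1.098), and Slc16a1 (-1.06), Eno1 (2.46) and Ldha (1.53) did so with normexp. That correction starts from the median pixel intensity, which for Eno1 and Ldha on the wild-type array was 5122.5 and 23844 against processed signals of 24800 and 66600. Ldha had a difference of -0.21, Eno1 one of -0.08 and Gapdh one of -0.33. The list's median of -0.10 lay at percentile 7.28 of matched lists, and it ranged from -0.17 to 0.12 over the other scalings, probe rules and deposited values. The highest of these came from the authors' deposited value table, in which 5 of the 22 members were at least 2-fold higher and the mean was 4.38, against -0.06 from the scanner signal. Without the departing probes described next, that table gave 19 members a median of -0.10 and a mean of -0.02, with 0 past 2-fold.

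That table followed the scanner signal closely except at a few probes. Among the 39030 probes with a single spot, 13 values of the wild-type column and 31 of the knockout column left the running median of probes of like signal by more than 0.5 on the log2 scale. All 13 and all 31 were whole numbers of log2 units away from it within 0.02. All 13 of the wild-type column lay below it, and in the knockout column 20 lay above and 11 below. For Ldha the wild-type value was 11 lower, for Eno1 it was 6 lower in the wild-type column and 14 higher in the knockout column, for Pdk1 and Gpi1 the knockout value was 24 and 32 higher, and for Hif1a and Foxp3 the knockout value was 7 and 6 lower. Of the 21 glycolysis genes with a single-spot probe in the table, 5 were affected, where 0.0340 would be expected from the 33 affected genes among 20372. The same probes stood out in other columns of the scanner files. Among single-spot probes well above background and without an outlier flag (21910 on the wild-type array and 25192 on the other), the background-subtracted signal left the running median by more than 0.5 on the log2 scale at 9 and 29 spots, and all of these were probes that depart in the value table of the same array. The values in this text come from the processed scanner signal unless the table or another column is named.

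**Figure D2:**
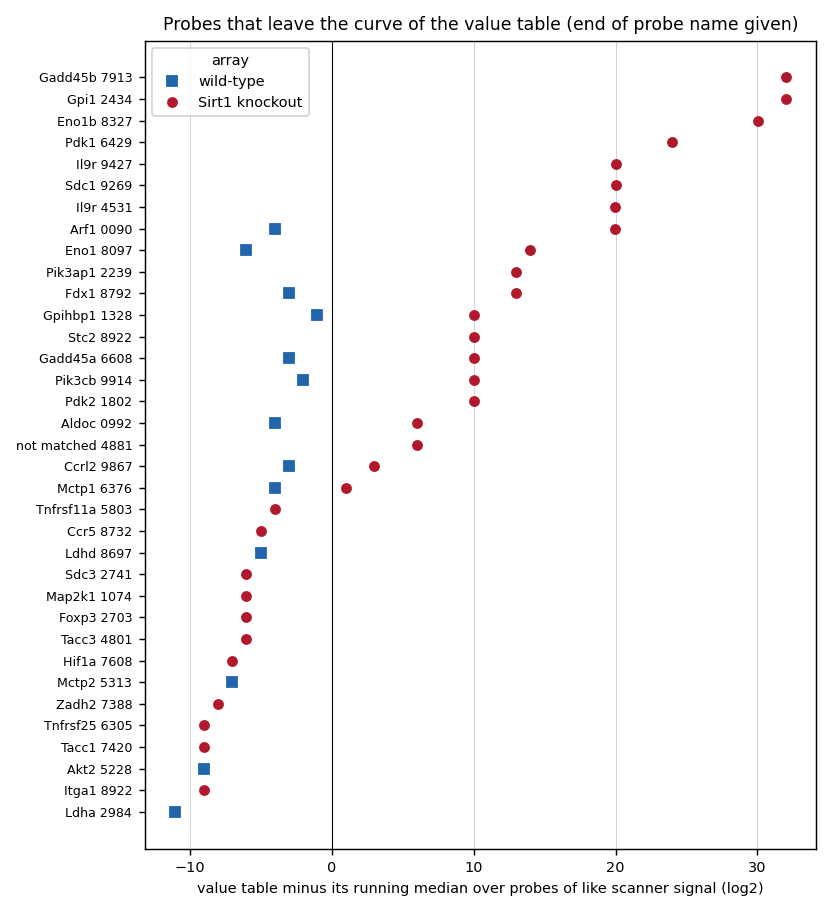
Departure (log2, horizontal axis) of the authors' deposited value from the running median of probes of like scanner signal, for the 35 single-spot probes that depart by more than 0.5 on either array, 1 row per probe. Blue squares are the wild-type column and red circles the knockout column, and the departures reach 11 below in the wild-type column and 32 above in the knockout column.

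Other metabolic lists had medians inside the matched range, and signal of other cell types limits them as it does glycolysis. HIF1 targets outside glycolysis had a median of 0.17 (percentile 90.4), and P4ha1, a collagen prolyl hydroxylase, was 2.62-fold higher by its brighter probe, a difference of 0.042 on the log2 scale with normexp, and 0.26 by the other. The tricarboxylic acid cycle and oxidative phosphorylation list had a median of 0.05 (percentile 54.9), and 16 of its 23 members differed by less than their scanner error. Cox5a at -0.49 and Idh2 at 0.40 differed most. Fatty acid oxidation had a median of 0.05 (percentile 53.1), with Hadh at -0.87 and Hadha at -0.65. In sterol and fatty acid synthesis, Scd1, a fatty acid desaturase, was 2.30-fold lower on the array labelled knockout, while the list's median was -0.10 (percentile 17.0). That list stood apart with normexp, with a median of -0.44 (percentile 1.46). The mTOR and amino acid uptake list had a median of 0.09 (percentile 61.3), and Sesn3, an inhibitor of mTOR complex 1, was 2.33-fold lower. The other sirtuins and NAD enzymes had a median of 0.02 (percentile 49.8), with Cd38, an NAD-consuming enzyme, at -0.93 and Nmnat3 at -0.85.

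Proliferation genes were lower on the array labelled knockout. All 23 were lower, 2 of them by at least 2-fold, and the median of -0.53 lay below all but 0 of the 10000 matched random lists. Top2a, the topoisomerase of dividing cells, was 2.83-fold lower and Ccnb1, cyclin B1, was 2.38-fold lower by its brightest probe, with its other probes at -0.84 and -0.68. The median kept its sign under every scaling, between -0.54 and -0.35. B cell markers were mostly lower on the same array, with a median of -0.22, and macrophage markers mostly higher.

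**Figure D3:**
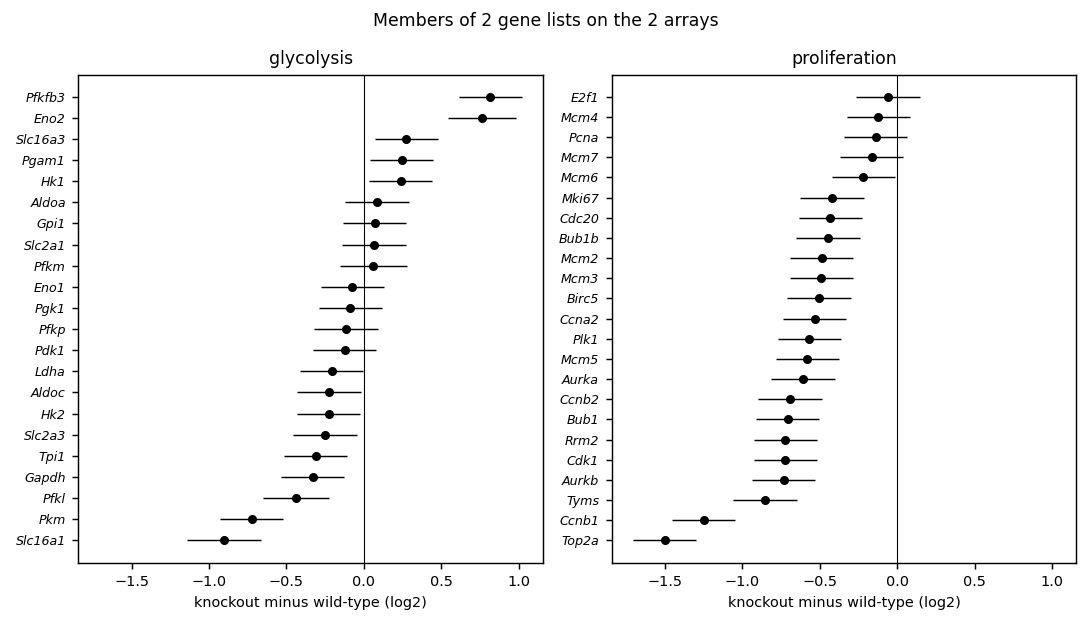
Difference between the arrays (knockout minus wild-type, log2, horizontal axis) for the 22 glycolysis genes and the 23 proliferation genes, 1 row per gene, with bars giving the scanner error of the difference between the 2 arrays. Glycolysis genes lie on both sides of 0 and all proliferation genes lie below it, down to -1.50 for Top2a.

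Stress lists were mixed. Heat shock genes were higher, 8 of 8 members measured on both arrays, with Hsph1, a chaperone of the HSP110 family, 2.46-fold higher and Bag3, a co-chaperone, 2.43-fold higher, and a median of 0.33 (percentile 98.4). The list no longer stood apart against random lists not matched on signal (percentile 94.1) or in the authors' deposited table (97.48). The medians of the macrophage and the red cell and stromal lists were higher on the same array. The p53 targets had a median of 0.20 (percentile 92.1): Sesn2, a stress-induced inhibitor of mTOR complex 1, was 3.35-fold lower, Ei24 was 2.22-fold lower and Cdkn1a, the p21 cell cycle inhibitor, was 2.26-fold higher, which turned to -0.50 on the log2 scale with normexp. NF-kB targets had a median of 0.17 (percentile 87.0), Nfkbia at 0.70 and Traf1 at 0.68 (1.04 and 1.03 with normexp). Among genes of the unfolded protein and amino acid stress responses, Pdia4, a chaperone of the endoplasmic reticulum, was 3.78-fold lower and Sdf2l1 was 2.03-fold lower, while the median was -0.07 (percentile 19.4). Type I interferon response genes had a median of -0.07 (percentile 9.68), with Ifit1 at -0.99 and Ifit3 at -0.78. The immediate early genes had a median of 0.04 (percentile 60.5). Fosb had a difference of -0.67 and Fos one of 0.26, and with normexp these were -1.21 and -0.55.

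Most markers of cells other than T cells were well above background on both arrays, at very different signals. All 12 B cell markers and all 14 matched markers of macrophages and dendritic cells were so, with Ms4a1 (CD20) at signals of 50400 and 35900 and Siglech, a marker of plasmacytoid dendritic cells, at 74900 and 67500 on the wild-type array and the array labelled knockout. Others were dimmer, such as Blk at 98.7 and 35.4, below the arrays' 75th percentiles of 584 and 558. The T cell identity list had a median difference of 0.04 (percentile 45.3), which turned to -0.11 with the mean over probes (percentile 10.6). Cd3e was 2.18-fold lower. The CD8 and NK cell markers were higher on the array labelled knockout in 9 of 10 members, with a median of 0.70 (percentile 99.98), and Klra1, an NK cell receptor, was 2.94-fold higher. Macrophage and dendritic cell markers were higher in 12 of 14 members, with a median of 0.40 (percentile 99.8), Mrc1 2.62-fold and Adgre1 2.34-fold higher, but with normexp the median of 0.27 lay just inside the central 95% (percentile 97.2). Mast cell, basophil and neutrophil markers were higher in 9 of 12 members, 3 of them by at least 2-fold, with a median of 0.32 (percentile 98.6). The list no longer stood apart in the authors' deposited table (percentile 97.4) or against random lists not matched on signal (96.5). Cpa3 was 3.30-fold and Fcer1a 2.80-fold higher, the latter with a difference of 0.030 on the log2 scale with normexp. Red cell and stromal markers were split, with 5 of 9 members higher and 4 lower. Their median of 0.44 (percentile 98.4) turned to -0.064 with normexp and to -0.045 with all members whatever their background flag, and the list did not stand apart by its mean (percentile 94.8). Col1a2 was 2.42-fold and Pdgfrb 2.32-fold higher, the latter at 0.55 on the log2 scale with normexp, while Alas2, an enzyme of haem synthesis in red cell precursors, had a difference of -1.15. B cell markers were lower in 11 of 12 members, with Blk 2.67-fold and Cd79a 2.27-fold lower and a median of -0.22 (percentile 2.82). Of the sex-linked genes, Xist was well above background on both arrays, with a difference of -0.81 by its brighter probe and -3.07 by the other, and Ddx3y, Kdm5d, Eif2s3y and Uty were not well above background on either.

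Over all genes the arrays were alike for most transcripts. Of 12958 genes well above background on both arrays, 512 were at least 2-fold higher on the array labelled knockout, 471 were at least 2-fold lower, and 92.4% lay within 2-fold. Genes at least 2-fold higher made up 52.1% of those past the threshold, and this share was 73.3% after centring on the median, 63.8% after quantile normalization, 61.3% after loess, 15.01% with normexp and 63.9% in the authors' deposited table, so the balance of directions is not settled. Of these, 371 of the higher and 379 of the lower genes had a mean signal below that of the median gene. A further 1758 genes were well above background on the array labelled knockout only and 142 on the wild-type array only, and of these 76 and 142 allowed a bound of at least 2-fold. The lowest signal well above background differed between the arrays, so these numbers do not compare the genotypes.

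**Figure D4:**
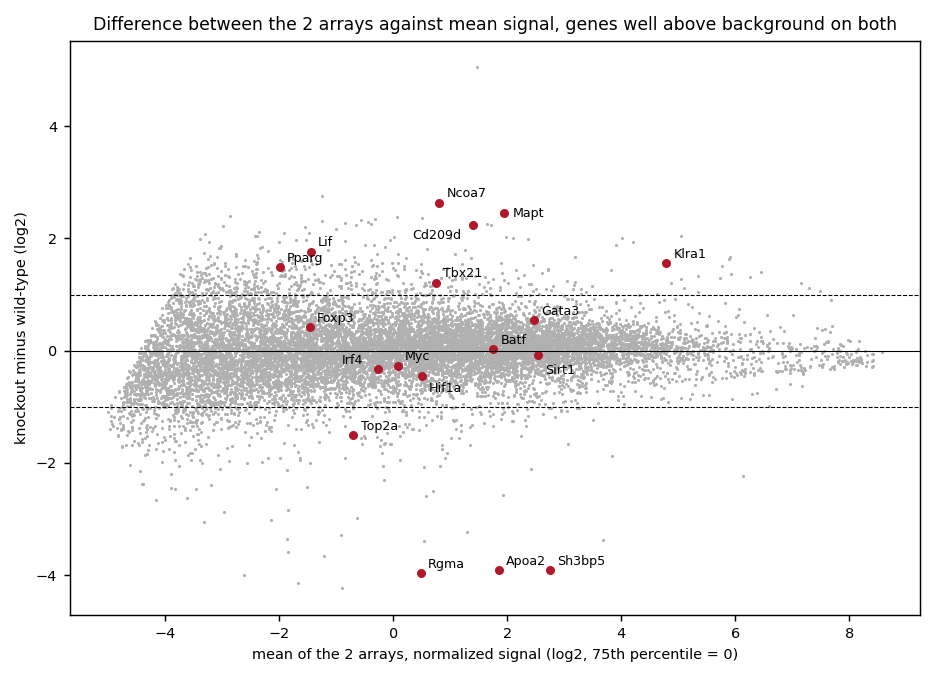
Difference between the arrays (knockout minus wild-type, log2, vertical axis) against the mean normalized signal of both arrays (log2, 75th percentile of each array at 0) for the 12958 genes well above background on both arrays, with dashed lines at a 2-fold difference. Red points are named genes, from Rgma at -3.97 to Ncoa7 at 2.64, and Sirt1 lies at -0.08.

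The largest differences among brighter genes fell on genes of many kinds. On the array labelled knockout Ncoa7, a nuclear receptor coactivator, was 6.23-fold higher, Mapt, the microtubule protein tau, 5.47-fold, Zfp13 5.21-fold and Prex2, a Rac exchange factor, 5.12-fold. Itga1, the integrin alpha 1 chain, was 4.77-fold higher by processed scanner signal, whereas the authors' deposited table gives -6.76 on the log2 scale from a probe that leaves its curve. On the array labelled knockout its processed signal was 3560 and its median intensity 3606, but its background-subtracted signal was 594.9. Cd209d, a C-type lectin of macrophages, was 4.74-fold higher, Gbp6, a guanylate-binding protein, 4.12-fold by its brighter probe and 0.32 on the log2 scale by the other, Rhox3a 4.09-fold, Cbr2 4.04-fold with a second probe at 2.08, Zfhx2 4.01-fold, Prr3 3.98-fold and Pip4p2 3.83-fold. Lower on that array were Rgma, a repulsive guidance molecule, 15.6-fold, Sh3bp5 15.1-fold, Apoa2, an apolipoprotein, 15.04-fold, Wwc1 10.5-fold, Wdr92 10.4-fold, Baiap2l2 9.44-fold, Krtap10-10 5.99-fold, Olfr544, an olfactory receptor, 5.69-fold, Rn28s1, the 28S ribosomal RNA, 4.70-fold, Tgfbr3l 4.31-fold, Cap1 4.19-fold and Ckmt1, a mitochondrial creatine kinase, 4.15-fold. All but Cbr2 and Gbp6 rest on a single probe well above background on both arrays. Ncoa7, Mapt, Itga1, Zfhx2, Apoa2 and Wdr92 also had other probes, which were not well above background on both arrays. Among all genes with several probes well above background on both arrays, the probes differed in the same direction for 59.8%. Among such genes past 2-fold this held for 44 of 58 that were higher and 45 of 58 that were lower.

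Genes above background on 1 array only gave bounds. Ren1, renin, was at least 11.6-fold higher on the array labelled knockout, Bpifb3 at least 6.04-fold, Cfd, complement factor D, at least 6.00-fold, Cidea at least 5.15-fold and Vegfc at least 4.08-fold. Ddx23, a spliceosomal helicase, was at least 14.5-fold lower there, Gk2 at least 11.9-fold, the olfactory receptor gene Olfr1080 at least 11.7-fold, Hoxc12 at least 10.8-fold and the olfactory receptor gene Olfr632 at least 8.10-fold. Each bound sets the signal on the brighter array against the lowest signal well above background on the other.

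The spread of repeated spots and the scanner error were small against a 2-fold difference. Repeated spots of the same probe had a median SD of 0.04 on the log2 scale on the wild-type array and 0.03 on the array labelled knockout over 248 probes, and the scanner error of a difference had a median of 0.20. For many bright genes this error was the same 0.204 whatever their signal, as for Rn28s1 and Sirt1. For those genes it is a fixed value and not a spread measured gene by gene, which also limits the counts of genes within their scanner error. The differences of a pair of probes of the same gene were a median of 0.29 apart over 2902 genes. All such probes of a gene differed in the same direction for 59.8% of these genes. None of these covers the spread between cultures or animals.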

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

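The authors' deposited value table drew attention because its values left the scanner signal they otherwise followed, a check chosen after the data were seen. Of 39030 single-spot probes, 13 in the wild-type column and 31 in the knockout column lay more than 0.5 away from the running median on the log2 scale, and every other single-spot probe lay within 0.37 of it. All of these departures were whole numbers within 0.02, from 0.999 to 11 in size in the wild-type column and from 1.004 to 32 in the knockout column. None of the spots behind them carried an outlier flag, and 9 probes departed in both columns. In the knockout column 13 values exceeded the highest log2 scanner signal of that array, and 0 did so in the wild-type column. Both Il9r probes, for the IL-9 receptor, stood 20 above the running median in the knockout column, while their scanner differences were 0.00 and -0.14. Aldoc was 4 below in the wild-type column and 6 above in the knockout column against a scanner difference of -0.23, and Akt2 was 9 below in the wild-type column against 0.16. Gadd45b stood 32 above in the knockout column against 0.05. The same probes drew attention in scanner columns that the comparisons do not use, also after the data were seen. The background-subtracted signal left the running median of spots of like processed signal by more than 0.5 on the log2 scale at 9 of 21910 spots on the wild-type array and 29 of 25192 on the array labelled knockout. The median pixel intensity did so at 7 and 0, and the spot extent lay outside 30 to 70 at 12 and 30, where all other probes lay between 36.1 and 65 on the wild-type array and between 35.2 and 65 on the other. Every one of these spots belongs to a probe that departs in the value table of the same array, which has 13 and 31 such probes. For Hif1a on the array labelled knockout the processed signal was 632, the median intensity 695.5 and the background-subtracted signal 239.2, and for Gadd45b these were 2550, 2681 and 22677. The error of the processed signal departed at 0 of these spots. The origin of these values was not tested.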

How the results depend on the processing

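No paired analysis was possible because each genotype had 1 array and no result came from a test. The values with only bright genes after loess, with 1-array members at their bound and from the authors' table without departing probes were chosen after seeing the data. The main counts of 512 higher and 471 lower genes became 801 and 292 after centring on the median, which moved the median difference of all genes from 0.00 to 0.19, and 205 and 1161 with normexp. They were 1096 and 4294 with no background filter, 141 and 92 for genes at or above the median signal, 142 and 92 for such genes after loess, 1420 and 1549 at 1.5-fold and 85 and 112 at 3-fold. With genes well above background on at least 1 array they were 1076 and 624. Quantile normalization, loess, the mean over probes, the authors' table and keeping outlier spots left both counts within 1.5 times. With loess 510 of the 512 higher and 371 of the 471 lower genes kept their call.

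The Sirt1 difference of -0.08 became 0.14 with normexp and stayed within its scanner error with quantile normalization, loess and the authors' table. Il9 exceeded the lowest signal well above background on 0 arrays, but on 2 with normexp and on 2 in the authors' table, where departing probes set that lowest value. Without those probes it was 0 again. Itga1 turned to -6.76 in the authors' table, and Il17rb to -0.063 and Cdkn1a to -0.50 with normexp. Of the other genes that the naming rule takes, 57 moved by more than their scanner error with normexp and 28 did not. With the mean over probes 6 of the genes with several measured probes moved and 3 did not. The authors' table moved 2, and quantile normalization and loess moved none by that much. Centring on the median shifts all genes alike, by less than any scanner error, and so does not test them. Among genes named as at least 2-fold different, Pparg (0.37), P4ha1 (0.042), Fcer1a (0.030), Pdgfrb (0.55), Lif (0.80), Klrg1, Bag3, Mrc1, S1pr1, Scd1, Sesn3, Ccnb1, Sdf2l1 and Cd3e lay within 2-fold with normexp, S1pr1, S1pr4, Ei24, Sdf2l1, Cd3e and Cd79a after centring on the median, and P4ha1 and Ccnb1 with the mean over probes. S1pr4 and Sdf2l1 did so with quantile normalization, loess and the authors' table as well, and Ei24 with quantile normalization and that table. Outside the authors' table, the genes of the rule and of glycolysis that passed 2-fold under another choice only were Slc16a1, Eno1, Ldha, Pfkfb3, Nfkbia, Traf1 and Fosb with normexp, Pfkfb3 and Havcr2 after centring on the median, and Xist with the mean over probes.

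The TH9 regulators left the central 95% with the mean (0.39), with all members (0.24) and with members at their bound (0.21). Other lists did so too: TH1 with normexp (0.20) and with only genes well above background on both arrays (0.22), sterol and fatty acid synthesis with normexp (-0.44) and the mean (-0.37), the unfolded protein and amino acid stress list with the mean over probes (-0.19) and the mean (-0.29), B cells with the mean (-0.44) and p53 targets with the authors' table (0.31). Lists that no longer stood apart were, with normexp, TH2 (-0.27), TFH (-0.021), cytokines (-0.35), macrophages (0.27) and red cells and stroma (-0.064). With the mean they were TFH (-0.21) and red cells and stroma (0.34), and with unmatched random lists TFH (-0.28), heat shock (0.33) and mast cells (0.32). The cytokine list fell inside the range with quantile normalization (0.33), loess (0.33) and the authors' table with or without departing probes (0.33 both), heat shock with that table (0.30), mast cells with it with or without those probes (0.31 both), and red cells and stroma with all members (-0.045). The proliferation, cytotoxic and CD8 and NK cell lists stood apart under every alternative, although centring on the median cannot change a list's percentile. The cause was not tested. Signal over background limits what dim genes can show: the dimmest eighth of genes had a median difference of -0.30.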

Other observations

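The tests on the T cell share and on fewer B cells in this part were chosen after the results they bear on were seen. The others address patterns already seen too, but were chosen before their own values were seen. The arrays differed in markers of lymphoid tissue that no comparison above covers. Markers of red pulp and lymph node macrophages were higher on the array labelled knockout in 10 of 10 measured members, 6 of them by at least 2-fold, with Marco at 1.43, Vcam1 at 1.35 and Timd4 at 1.18 on the log2 scale. Lymphoid stroma and endothelium markers were higher in 10 of 11 members measured on both arrays, with a median of 0.86, Lyve1 at 1.43 and Dcn at 0.92. Genes of T and B cell zones, most of them of antigen presentation and B cells, were lower in 9 of 12, with a median of -0.32 at percentile 0.0100, H2-Aa at -0.84, Ciita at -0.72 and Cd74 at -0.66. With normexp the median of the zone list was -0.031, still below the matched range (percentile 0.04). Plasma cell markers had a median of -0.07 (percentile 28.5), and organ-restricted genes one of 0.11 (percentile 72.2). With normexp the median of the organ-restricted genes was -0.96, inside its matched range of -1.11 to -0.87 (percentile 74.5). Members of this paragraph were chosen after their values were seen.

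Markers of B cells and myeloid cells stood well above background on both arrays, although the labels describe T cells sorted as CD4+TCR+CD62Lhi CD44lo, a gate that would remove them. Non-specific signal is argued against as the whole source, since 37.5% of the organ-restricted genes were well above background on both arrays, against 100.0% of the B cell and of the macrophage markers, but with 13 of 32 organ-restricted genes above it on the wild-type array and 20 of 32 on the other, some non-specific signal stays open. RNA of whole spleen or lymph node is a candidate explanation: 84.0% of the tissue macrophage and lymphoid stroma markers (21 of 25) were well above background on both arrays, with Marco at signals of 4650 and 12000, Dcn at 3280 and 5940 and Cxcl13 at 4070 and 5270. T cells can also express 2 of the 12 B cell markers, 2 of the 14 macrophage markers, 2 of the 12 tissue macrophage markers and 4 of the 13 stromal markers. Cells carried through the sort, other material on the arrays and a wrong sample label stay open, and no biological explanation was tested.

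The medians of the macrophage, mast cell and stromal lists were higher on the array labelled knockout, with 12 of 14, 9 of 12 and 5 of 9 members higher. A lower share of T cells there, with all other cell types in unchanged proportions, would raise the markers of every other cell type alike. B cell markers had a median of -0.22 against 0.40 for macrophages and dendritic cells. That gap of 0.62 exceeds the SD of 0.48 among the members of either list, and argues against this narrow form only. With normexp the medians lay at -0.09 and 0.27, less than 0.48 apart, so the argument depends on the background correction. Fewer T cells together with a changed mix of other cells stays open. The T cell identity list had a median of 0.04, which turned to -0.11 with the mean over probes. More macrophages of spleen or lymph node on the array labelled knockout is a candidate explanation, since their list had a median of 1.11, above the 0.31 that bounds matched random lists. That list cannot tell more such cells from more signal per cell. The rise was not particular to macrophages, since the lymphoid stroma and endothelium list had a median of 0.86. One member of the zone list stands in another list too, and 1 of the 13 mast cell and 1 of the 11 red cell and stromal markers can be expressed by T cells or their precursors. A difference between the genotypes and a difference between the tissue pieces or cultures behind the arrays stay open, since the design holds 1 sample of each.

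Proliferation genes were lower on the array labelled knockout. The background trend of dim probes is argued against as the whole cause, since the list's median of -0.53 lay below the -0.13 that bounds random lists matched on signal. Loess between the arrays removes the same trend. The median of -0.54 after loess, also below a bound of -0.13, therefore adds little. Fewer B cells on that array stays open: the B cell list had a median of -0.22 against -0.53, but that gap of 0.31 is smaller than the SD of 0.48 among its members. T cells express all 23 of the listed genes when they divide. The genotype and a difference between the cultures or samples stay open and untested.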
